A study of Meleagris gallopavo with 7 samples.

How the data were processed

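RNA was measured in 7 samples of blood leukocytes, 3 from 0 dpi and 4 from 2 dpi. Per the labels' protocols, blood was drawn into EDTA, leukocytes were caught with the LeukoLOCK system, total RNA was isolated, and indexed libraries were made with the TruSeq RNA v2 kit, which does not mark the strand. The authors deposited 1 file of whole-number counts per sample, with a gene symbol, a gene ID and a count for each of 23976 genes, per the file headers. The aligner, the counter, the genome build and the annotation are not given in the sources used here. All files list the same genes in the same order. The counts were used as deposited, with no row left out.

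Total counts per library ran from 13733081 to 35856191. Each pair of replicates differed by far more than sampling noise (chi-square per degree of freedom from 31.7 to 129), so no pair was the reads of 1 library split over 2 files; whether 2 libraries came from the same RNA or bird was not tested. The labels do not say whether the same birds were bled on both days or how many birds gave each sample, and p-values measure the spread between these samples.

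Of 23976 genes, 12604 are named by a LOC number in the files. A RefSeq gene table of the turkey (assembly Turkey_5.1), which matched 82.9% of the gene IDs, gave a symbol to 251 of them, and was used for names and for which genes neighbour each other, with no coordinates. No symbol matched for the globins, defensins and cathelicidins of the lists. IL1B, CATHL2, EXFABP, ALAS2 and ITGA2B matched no symbol and are not analysed here under those names. IL1RN, a member of the anti-inflammatory list that was called higher (adjusted p = 0.046; above 0.05 without 0 dpi replicate 3, 5 or 7 or 2 dpi replicate 2 or 8, and with upper-quartile factors, no filter beyond 1 count or limma-voom), carries IL1B as a synonym in that table, so which of these genes it is was not settled; it is named here after its values were seen. Without strand, reads of overlapping genes cannot be told apart, and copies of one gene family can share reads.

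The test (edgeR 4.0.16 in R 4.3.3, filterByExpr by group, TMM factors, glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p under 0.05) compared all 2 dpi with all 0 dpi libraries, with no covariate; filterByExpr kept 12677 genes, with its minimum count of 10. TMM factors were 0.798, 0.804 and 0.919 at 0 dpi and 0.981, 1.15, 1.36 and 1.10 at 2 dpi. Levels are CPM scaled by these factors, computed from the deposited counts, as mean ± SD over libraries. Fold changes are log2 values, 2 dpi against 0 dpi, and each SE is the log2 fold change divided by the square root of the F statistic. Principal components used log2 CPM with a prior count of 2.

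The test, the gene lists, the rule for naming genes and the main alternatives were set before the data were examined. There were 35 gene lists, covering blood cell types, possible contaminating tissues, and pathways of immunity, metabolism and cell stress. Lists with 5 or more tested members (33 of them) were tested with limma 3.58.1 camera on log2 CPM, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment. Named genes were the 8 largest rises and 8 largest falls among called genes with a symbol, a mean of 5 CPM or more and no overlap between groups; of each list with 3 or more called members, up to 4 with the smallest p and up to 2 of the less common direction; of other lists, up to 2 members; and 19 genes fixed by name. Of the called genes that this rule picked, 4 are counted in all totals and not reported here by name.

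The pipeline was tested on simulated counts for 12475 genes with the means, spreads and library sizes of these samples. At an adjusted p under 0.05 edgeR recovered 35 of 97 genes changed by 2-fold and 88 of 96 changed by 4-fold, and 8 of its 131 calls were false (6.11%). In the same simulation DESeq2 made 24 false calls of 158 (15.2%). The simulated genes varied independently of each other, with rises and falls set in equal number. The fall in the share of the most abundant genes was not modelled, nor was a spread that differs between the days. Pairs of replicates differed more at 2 dpi (chi-square per degree of freedom from 70.9 to 129) than at 0 dpi (31.7 to 57.6). The false shares belong to that setting and may differ in these data.

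Alternatives were DESeq2-type (RLE) and upper-quartile factors, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without quality weights, stricter thresholds, each library left out in turn, and, for lists, camera with an estimated correlation, fry and RLE scaling. All 35 splits of the libraries into 3 and 4 were fitted with the same test. Scores of single lists and differences between them were compared by 2-sided exact permutation tests, whose smallest p is 0.0286.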

Results

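Messenger RNA was measured in leukocytes from the blood of male turkeys of the Hybrid breed, aged 3 weeks. The series compared birds before inoculation (0 dpi) with birds 2 days after inoculation with Salmonella Typhimurium strain UK1 (2 dpi), and so asked which leukocyte genes differed after the challenge. The inoculum was 10 on the log10 CFU scale. There were 3 libraries at 0 dpi (replicates 3, 5 and 7) and 4 at 2 dpi (replicates 2, 4, 6 and 8). In the order of the replicate numbers, total counts were 29086147, 35856191 and 21525556 at 0 dpi and 27967304, 25502627, 13733081 and 29991736 at 2 dpi. Between 15222 and 16351 of 23976 genes had at least 1 count in a library. No uninoculated birds were sampled at the later day, so inoculation and the passage of 2 days were compared together.

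A few genes held much of the count of every library, and a smaller part of it at 2 dpi. The 3 most abundant held 50.5 ± 4.89% of counts at 0 dpi (SD, n = 3) and 30.2 ± 4.95% at 2 dpi (n = 4). These genes, LOC100539006, LOC100547252 and LOC100551072, carry no gene symbol in the files. In the reference annotation LOC100539006 and LOC100551072 lie beside MPG and NPRL3, and LOC100547252 lies beside RRM1 and STIM1, the surroundings of the alpha- and beta-globin genes in other vertebrates. Their log2 fold changes were -1.20 ± 0.33 (SE, adjusted p = 0.0464), -1.08 ± 0.31 (adjusted p = 0.0548) and -1.28 ± 0.27 (adjusted p = 0.0163). The second of these missed the threshold, and without 0 dpi replicate 3, 5 or 7 none passed it (adjusted p from 0.0508 to 0.251). They were picked out after their values were seen.

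The day of sampling was the main axis of variation between the libraries. The first principal component of log2 CPM held 45.4% of the variance, and the 0 dpi libraries lay between -44.3 and -35 on it. At 2 dpi, replicates 2, 4 and 8 lay between 25.3 and 55.4, and replicate 6 lay at 5.80, nearest to the 0 dpi libraries. The second component held 18.6% of the variance and spread the 2 dpi libraries from -34.5 to 42.9.

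**Figure D1:**
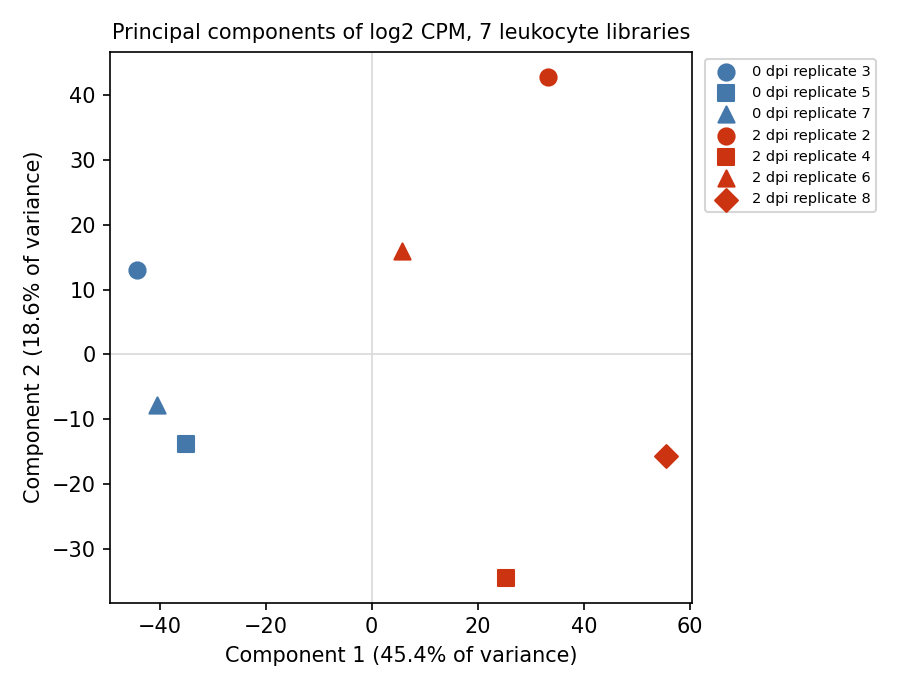
Principal components of log2 CPM of 12677 genes, with component 1 on the horizontal axis (45.4% of variance) and component 2 on the vertical axis (18.6%), 1 point per library, blue for 0 dpi and red for 2 dpi. The 0 dpi libraries sit at or below -35 on component 1, and 2 dpi replicate 6 sits between them and the other 2 dpi libraries.

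At 2 dpi some members of the interferon-induced and monocyte lists were higher and none lower, more members of the heterophil and cytokine lists were higher than lower, and some members of the red-cell and heme list were lower. These lists passed the set test limma camera with a preset correlation and did not with an estimated one (adjusted p of 0.525 to 0.53). ACOD1, which makes the antibacterial metabolite itaconate in activated macrophages, rose from 18.0 ± 2.92 CPM (SD, n = 3) to 518 ± 116 CPM (n = 4), a log2 fold change of 4.85 ± 0.25 (SE, adjusted p = 6.8e-06). IL4I1, a secreted amino acid oxidase that dampens T cells, rose from 0.189 ± 0.0478 to 83.7 ± 68.1 CPM (log2 fold change 8.72 ± 0.87, adjusted p = 0.000729). LYZ, the lysozyme of phagocyte granules, rose from 0.283 ± 0.0872 to 74.1 ± 80.4 CPM (7.97 ± 1.26, adjusted p = 0.00396), with 3.78 CPM in the lowest 2 dpi library and 190 in the highest. Of 12677 genes tested with edgeR's quasi-likelihood test, 800 were higher and 277 lower at 2 dpi at an adjusted p under 0.05. Of these, 524 of the higher and 201 of the lower carried a gene symbol, and 1073 of the 1077 had no overlap between the groups. No overlap was found for 21.7% of all tested genes, where chance gives 5.71%.

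The counts depended on single libraries and on scaling. Leaving out 0 dpi replicate 3, 5 or 7 gave 235, 407 and 361 genes higher and 65, 101 and 90 lower, and without 2 dpi replicate 6 or 8 there were 602 and 161 lower. Of all calls 74.3% were higher, against 98.0% with total counts and no scaling factor, which moved the median log2 fold change of all genes from 0 to 0.448 and gave 2738 genes higher and 56 lower.

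Other large rises were in single genes of varied function. IL22RA2, a soluble receptor that binds IL-22, rose from 0.140 ± 0.140 to 9.40 ± 4.46 CPM (6.02 ± 0.62, adjusted p = 0.000729). ASS1, the enzyme that remakes arginine from citrulline, rose from 11.8 ± 1.30 to 205 ± 76.6 CPM (4.12 ± 0.31, adjusted p = 0.000155). MLKL, the effector of necroptosis, rose from 20.2 ± 4.04 to 238 ± 117 CPM (3.55 ± 0.37, adjusted p = 0.000729). IL13RA2, a decoy receptor for IL-13, had 4 counts over the 0 dpi libraries and 10.1 ± 10.1 CPM at 2 dpi (7.38 ± 1.35, adjusted p = 0.00756; 0.0597 without 0 dpi replicate 3). SERPING1, the C1 inhibitor, rose from 11.1 ± 1.64 to 104 ± 113 CPM (3.23 ± 0.73, adjusted p = 0.0205), and its call was lost without 0 dpi replicate 3, 5 or 7 (adjusted p of 0.105, 0.0865 and 0.0845). LYZ and IL13RA2 also missed the threshold with limma-voom (adjusted p of 0.119 and 0.107), as did SERPING1 (0.0647).

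The largest falls were smaller than the largest rises. SCG3, a secretory granule protein, fell from 27.2 ± 2.11 to 3.19 ± 1.62 CPM (-3.09 ± 0.33, adjusted p = 0.000751). GRIN3B, a glutamate receptor subunit, fell from 17.2 ± 2.02 to 5.43 ± 0.519 CPM (-1.67 ± 0.19, adjusted p = 0.000859), and STK35, a kinase, from 55.3 ± 5.90 to 18.1 ± 5.44 CPM (-1.61 ± 0.21, adjusted p = 0.00158). IL17RD fell by 2.11 on the log2 scale, FECH by 1.89, ADA by 1.69 and PHLDA2 by 1.54, with adjusted p from 0.00719 to 0.0183. Those calls were lost without 0 dpi replicate 5 (adjusted p of 0.0848 for IL17RD), replicate 7 (0.0718 for IL17RD, 0.0570 for FECH) or replicate 3 (0.0697 for FECH, 0.0540 for ADA, 0.0557 for PHLDA2).

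**Figure D2:**
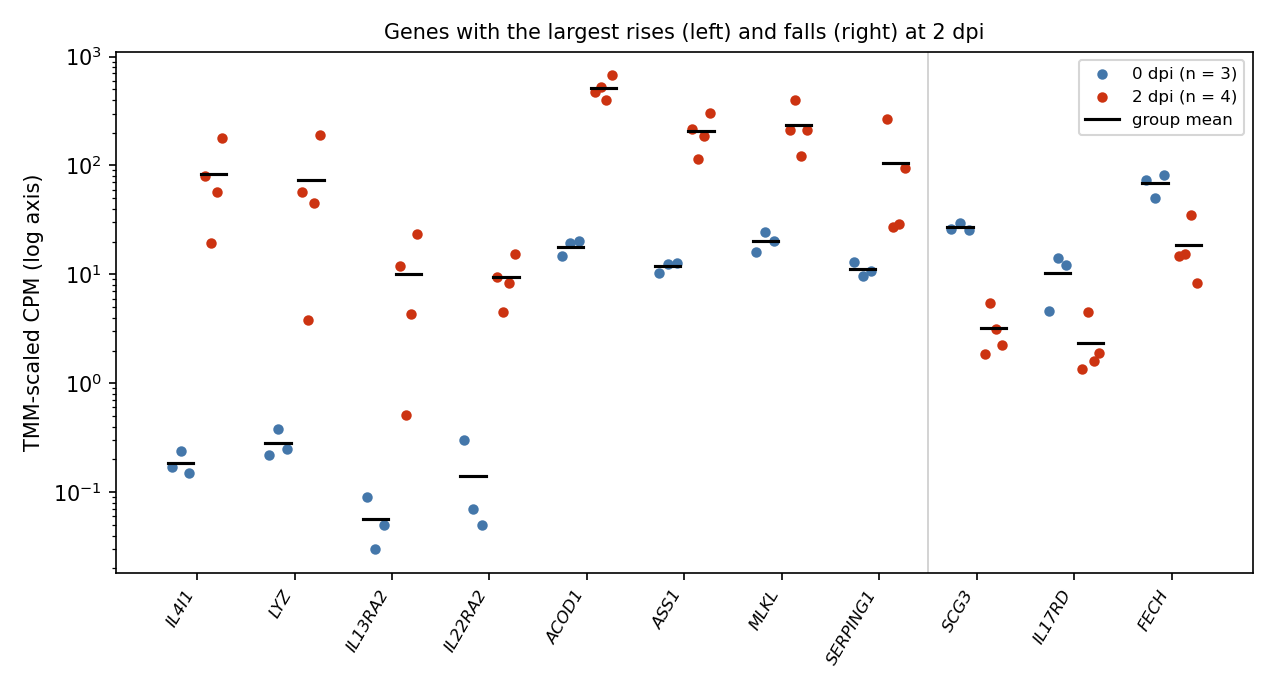
TMM-scaled CPM (vertical log axis) of the 8 genes with the largest rises and the 3 with the largest falls, 1 point per library, blue for the 3 libraries at 0 dpi and red for the 4 at 2 dpi, with black bars at the group means. Groups do not overlap for any of these genes, which was a condition of the choice, and LYZ at 2 dpi spans 3.78 to 190 CPM.

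Interferon-induced genes were higher in 11 of 26 tested members and lower in none (17 higher when adjusted over the list alone). A log2 fold change above 0 was found for 24 members, with a median of 1.08. SOCS1, a feedback inhibitor of cytokine signalling, rose from 3.67 ± 0.645 to 31.9 ± 17.9 CPM (3.12 ± 0.42, adjusted p = 0.00172). MX1, an antiviral GTPase, stayed low in count and rose from 0.199 ± 0.109 to 1.66 ± 0.819 CPM (3.06 ± 0.57, adjusted p = 0.00847; 0.0595 without 0 dpi replicate 3). Camera gave the list an adjusted p of 3.56e-08 with a preset correlation, and an adjusted p = 0.525 with an estimated correlation. There were 2, 6 and 5 members higher without 0 dpi replicate 3, 5 or 7. IFNG had no count in any library, which allows up to 0.0163 CPM over all libraries (3 counts, counting error only).

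Heterophils are the avian counterpart of neutrophils. Of 13 tested heterophil surface and migration genes, 8 rose and CXCR4 fell (10 and 1 when adjusted over the list alone), with a median log2 fold change of 0.95 over the list. CEBPB, a transcription factor of granulocytes, rose from 32.3 ± 4.26 to 131 ± 38.3 CPM (2.02 ± 0.24, adjusted p = 0.000992). ITGB2, the beta chain of leukocyte integrins, rose from 71.4 ± 7.33 to 169 ± 37.5 CPM (1.25 ± 0.19, adjusted p = 0.00337), and SLC2A6, a hexose transporter, had a log2 fold change of 1.72 ± 0.26 (adjusted p = 0.0028). CSF3R, the receptor for G-CSF, was the most abundant of those named and rose from 573 ± 90.9 to 1094 ± 234 CPM (0.93 ± 0.21, adjusted p = 0.0214), but missed the threshold without 0 dpi replicate 3, 5 or 7 (adjusted p of 0.108, 0.0524 and 0.116). CXCR4, a receptor that holds granulocytes in the marrow, was called with an adjusted p of 0.0461, and the call remained in 1 of 7 fits with a library left out. Camera gave an adjusted p of 2.6e-06 with a preset correlation, and an adjusted p = 0.525 with an estimated one. Leaving out 0 dpi replicate 3, 5 or 7 left 3, 6 and 5 members higher. Of the 34 heterophil granule and antimicrobial genes fixed, 5 were matched and 4 tested, of which LYZ rose (2 when adjusted over the list alone).

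Monocyte and macrophage markers were higher in 6 of 19 tested members and lower in none (10 higher and 1 lower when adjusted over the list alone; median log2 fold change 0.66). CSF1R, the receptor for macrophage colony-stimulating factor, rose from 58.0 ± 3.85 to 145 ± 18.5 CPM (1.32 ± 0.16, adjusted p = 0.000967). TLR4, the lipopolysaccharide receptor, rose from 19.6 ± 1.97 to 47.1 ± 4.53 CPM (1.27 ± 0.16, adjusted p = 0.00107), and IRF8, a transcription factor of monocytes and dendritic cells, from 83.9 ± 10.3 to 311 ± 149 CPM (1.89 ± 0.32, adjusted p = 0.00564). Camera gave the list an adjusted p of 0.00349 with a preset correlation, and an adjusted p = 0.53 with an estimated one. Members higher numbered 3, 3 and 4 without 0 dpi replicate 3, 5 or 7, and without 2 dpi replicate 2 or 6 there were 9 and 9; DESeq2 called 10, and edgeR 11 with total counts and no factor. Of 7 dendritic cell markers BATF3 was higher (log2 fold change 5.25 ± 0.71, adjusted p = 0.0017), from 4 counts over the 0 dpi libraries to 2.30 ± 1.31 CPM; this list had a median of -0.12 and a mean of 0.56. Camera with a preset correlation gave the dendritic cell list an adjusted p of 0.941.

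Proinflammatory cytokines, chemokines and receptors went both ways. Of 20 tested members 9 rose and 2 fell (12 and 3 when adjusted over the list alone), with a median log2 fold change of 0.88. IL8, the chemokine CXCL8 that draws granulocytes, rose from 1.15 ± 0.166 to 9.93 ± 4.41 CPM (3.10 ± 0.39, adjusted p = 0.00117). ALOX5AP, a protein needed for leukotriene synthesis, rose from 34.95 ± 3.35 to 110 ± 30.5 CPM (1.65 ± 0.22, adjusted p = 0.0016). The members lower were CXCR4 and IL12B, a subunit of IL-12 and IL-23, at 0.848 ± 0.0262 CPM at 0 dpi and 0.196 ± 0.143 CPM at 2 dpi (adjusted p = 0.0298). The call of IL12B was lost without any one of 0 dpi replicates 3, 5 and 7 and 2 dpi replicates 2 and 8 (adjusted p from 0.0554 to 0.108). Camera gave an adjusted p of 0.00868 with a preset correlation, and an adjusted p = 0.525 with an estimated one. Members higher numbered 2, 6 and 5 without 0 dpi replicate 3, 5 or 7. IL6 had 3 counts and IL10 had 13 over all 7 libraries and neither was tested.

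Anti-inflammatory and negative regulators, and pattern recognition and NF-kB genes, held more members higher and none lower. Among the former 7 of 26 tested members rose (7 when adjusted over the list alone). IL1RN, which carries IL1B as a synonym in the reference annotation, was 1 of them. They also included ACOD1, IL4I1, SOCS1 and SOCS3, the inhibitor of IL-6 type signalling, which rose from 16.8 ± 4.44 to 145 ± 66.4 CPM (3.11 ± 0.37, adjusted p = 0.000967). The median of that list was 0.14, and camera gave an adjusted p of 0.0832. Among the latter 6 of 33 members rose (9 when adjusted over the list alone; median 0.41). LY96, the partner of TLR4 in binding lipopolysaccharide, rose from 51.5 ± 7.24 to 194 ± 40.6 CPM (1.91 ± 0.20, adjusted p = 0.000751), and TNIP2, an inhibitor of NF-kB signalling, had a log2 fold change of 1.53 ± 0.20 (adjusted p = 0.00143). TLR5, the flagellin receptor, was at 0.774 ± 0.268 and 1.21 ± 0.408 CPM on the 2 days (adjusted p = 0.401). Camera gave the second list an adjusted p of 0.0101 with a preset correlation, and an adjusted p = 0.525 with an estimated one. Without 0 dpi replicate 3, 5 or 7 or 2 dpi replicate 4 there were 3 members higher in the second list, and the first list had 4 without 0 dpi replicate 3.

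Genes of red cells and heme synthesis were lower in 9 of 21 tested members and higher in none (12 lower when adjusted over the list alone), and the median log2 fold change was -0.76. RHAG, an ammonium channel of the red-cell membrane, fell from 423 ± 18.5 to 167 ± 28.7 CPM (-1.34 ± 0.17, adjusted p = 0.00128). UROD, an enzyme of heme synthesis, fell from 96.4 ± 37.4 to 36.3 ± 7.41 CPM (-1.41 ± 0.24, adjusted p = 0.0063). RHCE, a blood group protein, fell from 935 ± 151 to 447 ± 61.7 CPM (-1.07 ± 0.18, adjusted p = 0.00558), although with total counts and no scaling factor its adjusted p was 0.0586. Camera gave an adjusted p of 4.41e-08 with a preset correlation, and an adjusted p = 0.525 with an estimated one. Without 0 dpi replicate 3 or 7 there were 4 and 6 members lower, and with total counts and no scaling factor 4.

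No T or B cell marker was called in the main edgeR fit. With total counts and no scaling factor edgeR called 1 B cell marker higher and no T cell marker. Of 23 T cell markers none was past the threshold over all genes or over the list alone, although all 23 had a log2 fold change below 0 (median -0.71). edgeR gave 3 of them an unadjusted p under 0.05, DESeq2 called 0, limma-voom 0 and limma-voom with quality weights 1. CD3E, a chain of the T cell receptor complex, was at 47.1 ± 18.2 CPM at 0 dpi and 31.6 ± 18.9 CPM at 2 dpi (adjusted p = 0.458). Camera gave the T cell list an adjusted p of 0.000105 with a preset correlation, and an adjusted p = 0.664 with an estimated one. The mean log2 CPM of the list was 2.68 ± 0.53 at 0 dpi and 1.92 ± 0.70 at 2 dpi (SD), a difference with p = 0.171 in a 2-sided exact permutation test (0.205 when adjusted over the 6 lists so compared). None of the 6 passed this exact permutation test after adjustment: the heterophil surface and erythroid lists had p = 0.0286, the interferon-induced and monocyte lists 0.0571 (adjusted p of 0.0856 for each of these 4), and the B cell list 0.314. With 3 against 4 libraries the smallest p of this test is 0.0286, so after adjustment over 6 lists a pass was hard to reach. A miss here is thus weak evidence about any single list. Of 14 B cell markers none was called, and 2 had an unadjusted p under 0.05 in edgeR (DESeq2 called 1, limma-voom 1, and 1 with quality weights). CD79B, a chain of the B cell receptor, was at 22.8 ± 9.19 and 13.1 ± 10.1 CPM on the 2 days (adjusted p = 0.400). Camera gave the B cell list an adjusted p of 0.0617 with a preset correlation, 9.5e-05 without 2 dpi replicate 4 and 0.0209 without 0 dpi replicate 3, and an adjusted p = 0.777 with an estimated correlation and all libraries. Without 2 dpi replicate 4 there were 2 T cell and 3 B cell markers lower, and without replicate 6 there was 1 T cell marker.

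**Figure D3:**
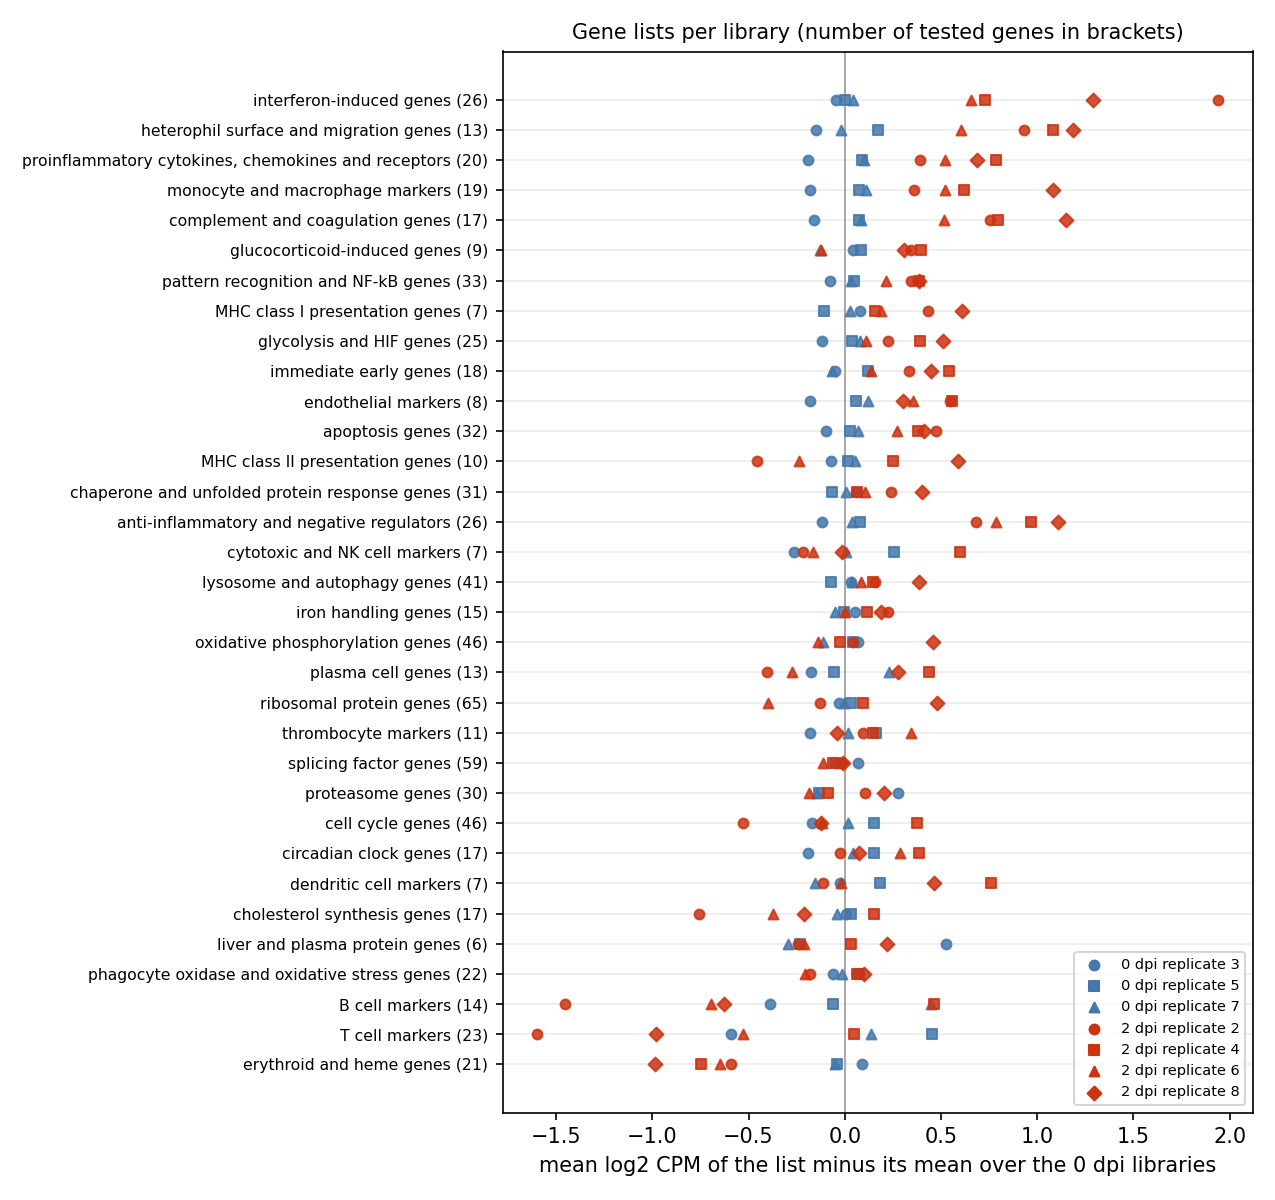
Mean log2 CPM of each gene list with 5 or more tested genes, minus its mean over the 0 dpi libraries (horizontal axis), 1 point per library, blue for 0 dpi and red for 2 dpi; lists are ordered by median log2 fold change. The 2 dpi libraries lie above all 0 dpi libraries for interferon-induced genes and below them for erythroid and heme genes, while T and B cell markers overlap between the days.

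Glycolysis and HIF genes, complement and coagulation genes, and apoptosis genes also held several members higher. In the glycolysis list 8 of 25 tested members rose and 1 fell (11 and 2 when adjusted over the list alone; median 0.36). PGK1, which makes ATP in glycolysis, rose from 38.1 ± 3.55 to 134 ± 35.9 CPM (1.81 ± 0.22, adjusted p = 0.000992), and ENO1, an enolase, from 144 ± 29.0 to 404 ± 130 CPM (1.49 ± 0.25, adjusted p = 0.00547). Leaving out 0 dpi replicate 3, 5 or 7 left 2, 2 and 3 members higher. In the complement list 3 of 17 members rose (7 when adjusted over the list alone), among them F3, tissue factor, with 6 counts over the 0 dpi libraries and 1.63 ± 0.610 CPM at 2 dpi (4.23 ± 0.54, adjusted p = 0.00125), and 1 did without any one 0 dpi library, 5 without 2 dpi replicate 2 or 6. Of 32 apoptosis genes 5 rose (10 higher and 2 lower when adjusted over the list alone), against 10 higher and 1 lower with DESeq2 and 14 higher with total counts and no factor. FAS, a death receptor, rose from 70.9 ± 12.7 to 179 ± 32.1 CPM (1.34 ± 0.19, adjusted p = 0.00254). Camera with a preset correlation gave adjusted p of 0.0639, 0.00558 and 0.0584 for these lists, and with an estimated correlation adjusted p of 0.53, 0.525 and 0.525.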

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

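The tests of other splits of the libraries, of red-cell genes with total counts and no factor, and of the 3 most abundant genes in 2 dpi replicate 6, were chosen after the results were seen. Genes higher at 2 dpi numbered 800, and 1 of the 35 splits of the libraries, the real one, gave as many (highest other 272). That other split set 2 dpi replicates 2, 4 and 8 against the rest, and 372 genes were higher in those replicates. The real split thus stood alone at 800. With 35 splits the smallest p is 0.0286, so chance is made unlikely for that count but not excluded. Genes past the threshold in either direction numbered 1077, again reached by 1 split, with 644 as the highest other. For the 277 genes lower, 2 of 35 splits gave as many, the real one and 1 with 372, so this measure as set does not exclude chance. The split with 372 put 2 dpi replicate 6 with the 0 dpi libraries. Its 372 genes are thus higher in the other 2 dpi libraries, against a group that holds the 0 dpi libraries. Genes lower in those 2 dpi libraries numbered 272 in that split, under the 277 of the real one. That split differs from the real one by replicate 6 alone, so it says little about chance. For the 9 gene lists past camera with a preset correlation, 14 of 35 splits gave as many (highest other 13), so chance cannot be excluded for that number.

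Red-cell and heme genes were lower at 2 dpi, with 9 of 21 tested members called. Total counts with no factor moved the log2 fold changes of all genes up by a median of 0.447 and left 4 of the 21 members called lower, which argues against scaling as the whole cause for those 4. For the other 5 the median log2 fold change went from -0.861 ± 0.161 (SD between members) to -0.401 ± 0.154; their calls ended because the folds shrank by about the shift of all genes, so their fall depends on the scaling. The 3 genes that hold up to 53.8% of a library were also left out of the scaling, with the ribosomal protein genes. All 9 members stayed called lower, and the log2 fold changes of all genes moved by a median of 0.005. This argues against the 9 calls resting on the presence of those genes in the TMM scaling. That test alone does not decide between TMM and total counts. The 3 genes held 50.5 ± 4.89% of counts at 0 dpi and 30.2 ± 4.95% at 2 dpi (SD). With total counts, such a fall by itself raises the combined share of all other genes, the direction of the median shift of 0.447. This argues against reading the 5 lost calls as a sign that those members did not fall relative to most other genes. A candidate explanation is a lower share of red-cell RNA in the fraction: 0 of 21 members fell further than the 3 most abundant genes in limma at an adjusted p under 0.05, as a smaller share would allow. FECH lay nearest to that limit (log2 difference -0.83, adjusted p = 0.156). Whether fewer red cells passed the leukocyte filter, fewer circulated, or each held less of these RNAs stays open, since the design holds no cell counts.

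At 2 dpi, replicate 6 lay between the 0 dpi libraries and the other 2 dpi libraries. It was the shallowest library, but with all libraries thinned to the same total its place on the first component was 0.577 (0 for the mean of the 0 dpi libraries, 1 for the mean of the other 2 dpi libraries), against 0.587 before, which argues against depth. A wrong label of a 0 dpi library is argued against as well, since 91.2% of the genes called higher without this library lay above every 0 dpi library in it. Of the genes called lower without it, 65.6% lay below every 0 dpi library in it. RNA of a 0 dpi bird mixed in would put genes higher and genes lower at the same fraction of the way to the other 2 dpi libraries. They were (0.502 and 0.495, a difference of 0.007), but a weaker response of all genes alike would do the same. Replicates 2 and 4 also had small differences (-0.046 and -0.024), and replicate 8 had 0.206. Those replicates were part of the mean they were set against. Equal fractions thus neither point to a mixture nor argue against it. The 3 most abundant genes were at 23.5% of counts, the lowest of all libraries. The other 2 dpi libraries held 30.0 to 35.3% and the 0 dpi libraries 44.9 to 53.8%. A mixture would give at least 37.5% if the unmixed sample were like the other 2 dpi libraries, so the share argues against a mixture with such a sample. That profile is assumed, and a mixture with a sample that held less of these genes is not excluded. A weaker or slower response in the birds of this sample may also be the explanation, and it was not tested.

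T cell markers lay below their 0 dpi level on average, yet their spread at 2 dpi was wide, with replicate 4 at 2.73 and replicate 2 at 1.08 in mean log2 CPM. A candidate explanation is dilution of all lymphocytes alike by RNA of other cells. T cell minus B cell markers differed between the days by -0.186 (exact permutation test, p = 0.543), so the lists were not seen to move apart. With 3 against 4 libraries and lists of this spread, a small gap could have been missed, so this does not decide for dilution. The B cell list itself was not shown to fall (p = 0.314 in the exact permutation test). A fall in the number of T cells and a change of expression within them stay open, and the difference in the T cell list itself had p = 0.171 in the exact permutation test.

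Of 148 values, 11 (7.43%) had a 2 dpi library far from the other 3, where chance flags about 1 in 20 such groups. The gap of that library to its nearest neighbour, as a part of the group's range, was as follows. Replicate 8 stood apart for RHAG (0.915; 124 CPM against 179 to 184), C1QA (0.878; 142 against 37.7 to 50.4), ENO1 (0.837; 597 against 318 to 363) and PDIA3 (0.832; 333 against 181 to 207). Replicate 4 stood apart for STK35 (0.900; 26.2 against 14.9 to 16), IL12B (0.867; 0.41 against 0.11 to 0.15), TNNT3 (0.849; 7.91 against 4.39 to 4.92), DUSP1 (0.837; 20.8 against 13.9 to 15.1) and E2F8 (0.834; 11.97 against 3.24 to 4.69). Replicate 6 stood apart for PSMD12 (0.905; 22.6 against 26.2 to 26.6) and for the mean log2 CPM of glucocorticoid-induced genes (0.834; 3.65 against 4.08 to 4.17).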

How the results depend on the processing

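Scaling with total counts and no factor, and scaling without the 3 most abundant and the ribosomal protein genes, were chosen after the data were seen. The planned scaling without hemoglobin genes was not run as written, since no symbol in the files names one. The 800 genes higher and 277 lower became 2738 and 56 with total counts and no factor, and 311 and 55 at an adjusted p under 0.01. Genes lower numbered 517 with DESeq2 (504 genes had no adjusted p), 561 with limma-voom and quality weights, and 121 at a fold change of 2 or more. Leaving out 1 library gave 235 to 1015 genes higher and 65 to 602 lower, the lowest without 0 dpi replicate 3 and the highest without 2 dpi replicate 6. Fewer samples can lower such counts, but 407 and 361 genes were higher without 0 dpi replicate 5 or 7. The causes of these shifts were not tested. For total counts, the smaller share of the 3 most abundant genes at 2 dpi by itself raises the combined share of all other genes. RLE and upper-quartile factors, both filters, limma-voom and the scaling without abundant genes kept both counts within 1.5 times. No called gene changed sign in any of these fits, and of the 277 genes lower, 56 stayed called with total counts and no factor. Of the 9 lists past camera, 0 passed with an estimated correlation (0.0135 to 0.754 in these lists). With fry 5 of these 9 passed (not the interferon-induced, monocyte, T cell and immediate early lists, with adjusted p of 0.0669, 0.0658, 0.299 and 0.0808), as did the anti-inflammatory and apoptosis lists. With RLE scaling the same 9 passed. With 1 library left out 9 to 13 lists passed, and the immediate early list was lost without 0 dpi replicate 7 (0.0561) or 2 dpi replicate 4 (0.0567). With total counts and no factor, members higher went from 11 to 24 in the interferon-induced list, 6 to 17 in pattern recognition, 3 to 10 in complement, 8 to 13 in glycolysis, 6 to 19 in lysosome, 2 to 14 in chaperone and 4 to 8 in immediate early genes. Members lower went from 3, 2 and 2 to 0 in the phagocyte oxidase, iron and splicing lists. Members higher in these 3 lists went from 4, 2 and 0 to 6, 5 and 10. DESeq2 called 5 complement and 6 chaperone genes higher. Of 82 named genes past the threshold, 61 stayed past it in every alternative with all libraries, 37 in every fit with a library left out, and 35 in both. Without 0 dpi replicate 3, 44 of the 82 were lost. With total counts and no factor, LGMN (0.013) and PSMD12 (0.047), not called in any fit, had log2 fold changes above 0 in place of below. No paired analysis was possible because the replicate numbers of the days do not overlap. With 3 against 4 libraries, 2-fold changes were often missed in simulation, so genes not called are not shown to be unchanged.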

Other observations

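Iron handling genes went both ways at 2 dpi, with 2 of 15 tested members higher and 2 lower (3 and 4 when adjusted over the list alone). SLC40A1, the iron exporter ferroportin, rose from 611 ± 67.6 CPM (SD, n = 3) to 1517 ± 468 CPM (n = 4) (log2 fold change 1.31 ± 0.24, SE, adjusted p = 0.00767; 0.0652 without 0 dpi replicate 3). SLC11A1, the phagosomal metal transporter NRAMP1, was at 8.39 ± 0.798 and 16.03 ± 5.52 CPM (adjusted p = 0.0491), and 2 of 7 fits with a library left out kept the call. NCOA4, the receptor that sends ferritin to lysosomes, fell by 0.91 on the log2 scale (adjusted p = 0.0137; 0.0784 without 0 dpi replicate 3 and 0.0760 without replicate 7), and HEBP1, a heme-binding protein, by 0.76 (adjusted p = 0.0122; 0.0602 and 0.0764); neither was called with total counts and no scaling factor. Phagocyte oxidase and oxidative stress genes also went both ways, with 4 of 22 higher and 3 lower (5 and 7 over the list alone; median -0.28). Without 0 dpi replicate 3 none of these calls in either list was made. Camera with a preset correlation gave adjusted p of 0.923 for the iron list and 0.318 for the phagocyte oxidase list. GPX4 and TXN, antioxidant proteins, fell by 0.90 and 0.84 (adjusted p of 0.0102 and 0.0128); both of these calls were lost without 0 dpi replicate 3 or 5 and with total counts and no factor.

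Lysosome and autophagy genes were higher in 6 of 41 tested members and lower in none (6 over the list alone), with 1, 3 and 2 higher without 0 dpi replicate 3, 5 or 7. CTSC, the protease that activates granule serine proteases, rose from 52.6 ± 9.55 to 229 ± 89.8 CPM (2.12 ± 0.28, adjusted p = 0.00145). Immediate early genes were higher in 4 of 18 (4 over the list alone; camera adjusted p of 0.022 with a preset correlation, and an adjusted p = 0.53 with an estimated one), but 1 was called without 0 dpi replicate 3, 5 or 7 or without 2 dpi replicate 2 or 4, and 2 without replicate 8. Of these, RGS2, a brake on G protein signalling, rose by 1.88 ± 0.21 (adjusted p = 0.000821). HSD11B1, which turns inactive glucocorticoid into its active form, was the member called of 9 glucocorticoid-induced genes (1.39 ± 0.20, adjusted p = 0.00261). That list had 2 members higher with limma-voom and quality weights or without 2 dpi replicate 6, and 5 with total counts and no factor. Circadian clock genes were higher in 3 of 17 (4 over the list alone; median -0.12, mean 0.23), with 0 called without 0 dpi replicate 3 and 1 without replicate 5 or 7. Cholesterol synthesis genes were lower in 3 of 17 (3 over the list alone), among them SQLE, squalene epoxidase, which fell by 1.33 (adjusted p = 0.00703; 0.0508 without 0 dpi replicate 3); without 0 dpi replicate 3, 5 or 7 or 2 dpi replicate 8 there were 0, 1, 1 and 1. Camera with a preset correlation gave adjusted p of 0.169, 0.288, 0.617 and 0.0584 for the lysosome, glucocorticoid-induced, circadian clock and cholesterol lists.

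The other lists held few calls. Calls were 2 higher of 31 chaperone and unfolded protein response genes, 2 of 13 plasma cell genes (PDIA4 and CRELD2 in both), 2 of 8 endothelial markers (PECAM1 and ERG) and 1 of 7 cytotoxic and NK cell markers (CST7). PECAM1 is also carried by leukocytes and thrombocytes. Calls were 2 lower of 59 splicing factor genes (SRSF5 and SRSF1) and 1 of 6 liver and plasma protein genes (SERPINC1). Without 0 dpi replicate 3 the call of PECAM1 remained and these others were lost. None of the lists of these calls passed camera with a preset correlation (adjusted p from 0.133 to 0.941). Of all 12677 tested genes, 800 were called higher and 277 lower, so a few calls in a list can arise at that rate. edgeR called none of 11 thrombocyte markers, 7 MHC class I and 10 MHC class II presentation genes, 46 cell cycle genes, 65 ribosomal protein genes, 46 oxidative phosphorylation genes, 30 proteasome genes and 4 muscle markers. At an unadjusted p under 0.05 it gave 4, 3, 2, 7, 0, 3, 0 and 1 of these, DESeq2 called 2, 0, 1, 4, 0, 2, 0 and 0, limma-voom called 1 thrombocyte marker and none of the others, and with quality weights it called 2, 1, 1, 3, 0, 2, 0 and 0. With total counts and no factor edgeR called 3, 6, 2, 2, 6, 13, 11 and 1 of them, all higher. Without 2 dpi replicate 6 it called 2 thrombocyte markers lower and 1 MHC class II, 1 cell cycle and 3 oxidative phosphorylation genes higher, and without replicate 2 there were 1 thrombocyte marker, 1 MHC class II, 2 cell cycle and 1 oxidative phosphorylation genes. Medians of the T cell and the erythroid lists stayed below 0 with total counts and no factor (-0.22 and -0.31), while that of the B cell list moved from -0.30 to 0.14.

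An unnamed gene held a larger part of the counts at 2 dpi. LOC100544929 held 0.30 ± 0.04% of counts at 0 dpi (SD, n = 3) and 1.49 ± 0.52% at 2 dpi (n = 4), with a log2 fold change of 1.89 ± 0.32 (SE, adjusted p = 0.00579; 0.0549 without 0 dpi replicate 3). In the reference annotation it lies between NPDC1 and C8G. It was picked out after its values were seen, and what it encodes was not settled here.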
